A study of Mus musculus with 18 samples.

How the data were processed

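DNA from tails of 9 mice of the C57BL/6 strain was hybridised to Agilent oligonucleotide arrays, each mouse against 1 reference male of the same colony on 2 arrays with exchanged Cy3 and Cy5 labels. Groups were taken from the labels: male parent (1 mouse), female parent (1 mouse) and progeny (7 mice). Per the labels' protocols, DNA was extracted by the Kurabo PI-50a tissue procedure and labelled by version 4.0.8 of Agilent's protocol for genomic DNA on oligonucleotide arrays. Per the file headers, Feature Extraction 10.7.1.1 with the CGH_107_Sep09 protocol was used on a design of 973116 features, of which 966371 were not controls, with positions on build mm9. The linear intensity of each spot was deposited by the authors as processed signals of both dyes, background-subtracted and linearly dye-normalized by Feature Extraction per the file headers, and as median and background intensities. A log10 ratio of Cy5 over Cy3 was also deposited for each spot, per the file headers. The value table of the series holds log2 ratios deposited by the authors, and its comparison with each array showed reference over mouse on every array, with a correlation of 1 with the scanner ratio where the mouse was in Cy3 and -1 where it was in Cy5, and column medians between -0.010 and 0.013. Its scale and direction are thus settled by the dyes in the labels, and the small offset of its centring was not stated in the sources used here.

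Per spot, the log2 ratio of mouse over reference was computed from the processed signals, outlier-flagged spots and controls were left out, spots of one probe were averaged, and each array was centred on its autosomal median, without loess or quantile normalization. This gave 950749 probes, of which 36 on unplaced sequence were not used. Every array passed the range check of the scanner software. Spots not well above background were 0.060% to 1.04% of an array, 0 spots were saturated, and the SD of neighbouring log ratios reported in the headers was 0.164 to 0.220. The median signal was 2.80 to 5.84 times the background. Both arrays of a mouse were averaged and count as 1 sample. Over autosomal probes, the turned ratios of both arrays of a mouse correlated at -0.35 to -0.20, since probe-specific dye effects exceed the differences between mice. These effects cancel in the mean of both orientations. The ratio's direction comes from the dyes in the labels.

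Intervals were found by a search for runs of probes with the highest score, the sum of log2 ratios divided by the noise times the root of the number of probes. The noise was the median absolute deviation of neighbour differences. An interval needed a score of at least 6, at least 3 probes, an absolute mean of at least 0.25 over both arrays and of at least 0.15 with the same sign on each array. Overlapping intervals of different mice were joined into regions, and a mouse was called in a region if it met the mean conditions there. As a guide to false calls, the search was repeated on the dye-only signal (the difference between both arrays in place of their mean) and on 3 random orders of the probes. The noise of the dye-only signal was 0.150 to 0.173, against 0.099 to 0.123 for the mean, and it keeps the probe-specific dye effects. Its counts are thus no direct estimate of false calls in the mean, and random order removes any pattern along the genome. On simulated segments placed in shuffled data of the 9 mice (950622 probes searched), the caller recovered 98% of 3-probe segments shifted by 0.58 and 13% of those shifted by 0.3, and 95.4% of 10-probe segments shifted by 0.3. Regions to be named were fixed before the data were examined as the up to 10 with the highest interval score among those shared by all 9 mice, called in a parent, or called in progeny only. Other regions are named as chosen after their values were seen, among them those of at least 10 probes and the 10 with intervals in the same 4 mice.

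Progeny were tested against the reference and against parents with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg), 1 value per mouse, on the 950010 autosomal probes with a value on all 18 arrays, after 612 were left out. On simulated values with the spreads of the data and 200 changed probes, the fit against the reference recovered 92% of probes shifted by 0.58 and 55% of those shifted by 0.3, with 5 false calls. Passage from parents was tested with an exact two-sided binomial test against 0.5. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0 were used. Alternatives fixed before the data were examined were normexp correction (offset 50) of the median signals, the scanner's own log ratio, the value table, a filter on dim probes, other scores, lengths and minimums, single dye orientations, another overlap, another noise estimate, leaving out mice, a fit on 18 arrays with the mouse as a random block, and scan day as a random block. Normexp used median signals in place of the planned mean signals, which were not used here. Correction for GC content was not run and genes were not named, because the gene table at hand is on another build than the arrays. For the same reason the planned test of gene lists was not run.

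Each array was on its own slide. Scan dates gave 5 days: both parents on day 1, progeny 1 and 2 on day 2, progeny 3 and 4 on day 3, progeny 5 and 6 on day 4 and progeny 7 on day 5.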

Results

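Copy number was profiled in 1 family of C57BL/6 mice by comparative genomic hybridization, in which tail DNA of a mouse and DNA of a reference animal are labelled with different dyes and hybridised together to oligonucleotide probes, so that the ratio of both colours at a probe follows the ratio of DNA copies. The family held 1 male parent, 1 female parent and 7 progeny, and each of the 9 mice was set against the same reference male on 2 arrays with exchanged dyes. The 18 arrays thus gave 1 value per mouse and probe, and the SD between both arrays of a mouse is technical. The series title names male mice that received gamma rays at 1 mGy per day for 400 days, whereas the design text calls the male of this family non-irradiated, so no irradiation status is assigned to the male parent here. No family with a different exposure was analysed here, and the data therefore compare family members only. All values are log2 ratios of mouse over reference, and positions are on mouse build mm9. After spots of one probe were averaged, 950622 autosomal probes with a median spacing of 2053 bp remained, together with 68 probes of chromosome X and 23 of chromosome Y. The number of arrays limits the precision of every value.

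The female parent, set against a male reference, gave the response of the arrays to a known difference in copies. Its mean log2 ratio over chromosome X was 0.95 ± 0.04 (SD of 2 arrays), which is 1.94-fold, near the 2-fold difference between females and males. Over chromosome Y it was -2.96 ± 0.0044, so that the reference signal was 7.79-fold higher. The male parent gave 0.0025 ± 0.07 on X and -0.04 ± 0.16 on Y. The labels do not state the sex of the progeny. Progeny 5, 6 and 7 had X ratios of 0.97, 0.96 and 0.95 and Y ratios of -3.30, -2.93 and -3.16, and the X ratios of progeny 1 to 4 lay between -0.04 and 0.03. The Y value of the female parent became -1.26 when only probes well above background on every array were used and -0.70 after normexp background correction. That filter drops a probe that is dim in either dye on any array, so low Y signal in a mouse itself removes Y probes. The value of -1.26 thus cannot show whether dim probes distort the Y ratio.

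Regions at which every member of the family stood apart from the reference male were sought because all arrays share that animal. A segment of 27.9 kb on chromosome 7 (133217428 to 133245332, 17 probes) was lower in all 9 mice, at -0.40 ± 0.03 (SD, n = 9). A segment of 24.4 kb on chromosome 15 (8343077 to 8367454, 12 probes) was also lower in all 9 mice, at -0.53 ± 0.04 (SD, n = 9). These 2 regions met the call conditions in every mouse. A pair of longer segments had an interval in each of the 9 mice but failed the minimum of 0.25 in some mice once overlapping intervals were joined. On chromosome 12 (56179547 to 56392570, 44 probes) the mean was 0.24 ± 0.02 (SD, n = 9) and 5 mice were called, and on chromosome 14 (53387255 to 54393560, 112 probes) it was -0.24 ± 0.01 (SD, n = 9) and 3 mice were called. The ratios of the 9 mice spanned 0.21 to 0.26 on chromosome 12 and -0.26 to -0.22 on chromosome 14, so both segments differed from 0 by far more than the spread between mice. With a single reference animal, its own deviation cannot be separated from that of the family.

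**Figure D1:**
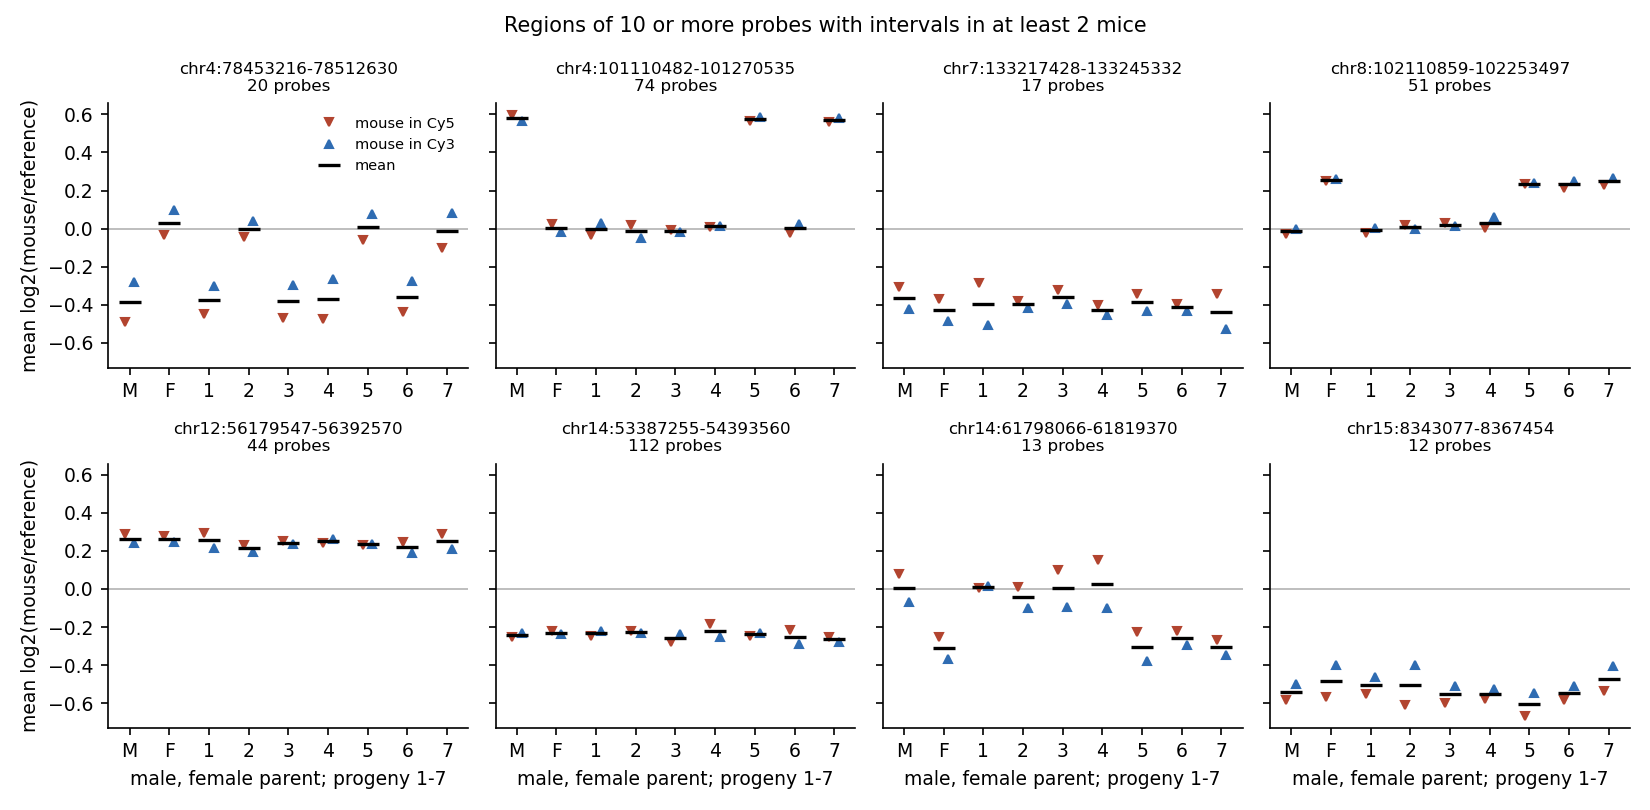
Mean log2 ratio of mouse over reference (vertical axis) for the male parent (M), the female parent (F) and progeny 1 to 7 (horizontal axis) at the 8 regions of 10 or more probes with intervals in at least 2 mice; triangles are the arrays with the mouse in Cy5 (down) or Cy3 (up), and bars their mean. The chromosome 4 gain stands at 0.58, 0.58 and 0.57 in the male parent, progeny 5 and progeny 7, while the chromosome 7 and 15 losses are seen in all 9 mice.

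The limma comparison of the 7 progeny with the reference male found the same segments probe by probe. Of 950010 autosomal probes, 117 passed an adjusted p of 0.05 (Benjamini-Hochberg) with an absolute log2 ratio of at least 0.25, of which 26 were higher and 91 lower. Of these, 90 lay in the 4 segments above: 14 on chromosome 7, 18 on chromosome 12, 48 on chromosome 14 and 10 on chromosome 15. The first-ranked probe, on chromosome 14 at 53759005, had a log2 ratio of -0.64 ± 0.03 (SE, adjusted p = 2.42e-05) with the same sign in 7 of 7 progeny. A ratio against 1 reference mouse leaves out that mouse's own spread. The fit on all 18 arrays with the mouse as a random block and a dye term called 177 probes, while leaving out progeny 5 left 77. In the 18-array fit the correlation between the arrays of a mouse was estimated at 0.0094. It thus weighed both technical arrays almost as separate samples, and its count is not based on 1 value per mouse.

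Progeny were compared with parents to ask whether any probe shifted in the progeny as a group. No autosomal probe passed (0 of 950010, limma, smallest adjusted p = 0.647), while 38611 had an unadjusted p under 0.05. The median SE of the progeny minus parents difference was 0.08, and on simulated data with the same spreads the fit recovered 27% of probes shifted by 0.58 and 0% of those shifted by 0.3. Only 2 parents entered, both scanned on day 1, whereas the progeny were scanned on days 2 to 5. With scan day as a random block 0 probes passed, but no day held both parents and progeny. The block therefore cannot separate day from group. The correlation within days was estimated at -0.0065, so the block hardly acted. A single probe passed without progeny 3, and a single one without the female parent, a fit in which the lone parent is assumed to vary like the progeny.

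The passage of parental changes to the progeny was examined at regions called in exactly 1 parent. The longest was a gain of 160 kb on chromosome 4 (101110482 to 101270535, 74 probes), at 0.58 ± 0.02 (SD of 2 arrays) in the male parent and 0.0044 ± 0.03 in the female parent. Progeny 5 and 7 carried it at 0.58 ± 0.02 and 0.57 ± 0.02, and the other five lay between -0.014 and 0.011. A loss of 59.4 kb on the same chromosome (78453216 to 78512630, 20 probes) was -0.39 ± 0.15 in the male parent and 0.03 ± 0.09 in the female parent. It recurred in progeny 1, 3, 4 and 6, at -0.37, -0.38, -0.37 and -0.36. With 2 and 4 carriers among 7 progeny, neither share differed from 0.5 (exact two-sided binomial p = 0.453 and p = 1).

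At further regions the ratio of the female parent departed from 0 and that of the male parent did not. Of these regions, 10, on 9 chromosomes, had intervals in progeny 5, 6 and 7 and in no other progeny. The largest by value was a loss on chromosome 3 (25417435 to 25432738, 3 probes), at -1.63 ± 0.18 in the female parent and -1.58, -1.61 and -1.68 in these progeny, against -0.02 ± 0.15 in the male parent. The longest was a gain of 142.6 kb on chromosome 8 (102110859 to 102253497, 51 probes), at 0.26 ± 0.01 in the female parent and 0.24, 0.23 and 0.25 in these progeny. These progeny values fell just under the call minimum, so the joined region counted as called in 0 of 7 progeny although each of the 3 had an interval inside it. Losses of the same distribution lay on chromosome 6 (104236953 to 104246570, female parent -0.76 ± 0.17), chromosome 3 (132546474 to 132553080, -0.52 ± 0.17), chromosome 9 (35853071 to 35865189, -0.40 ± 0.08) and chromosome 14 (61798066 to 61819370, -0.31 ± 0.08). Progeny 5, 6 and 7 are also the progeny with raised X and lowered Y ratios. The 10 regions thus followed the X and Y ratios of the mice, and cannot be read as autosomal changes passed on independently.

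**Figure D2:**
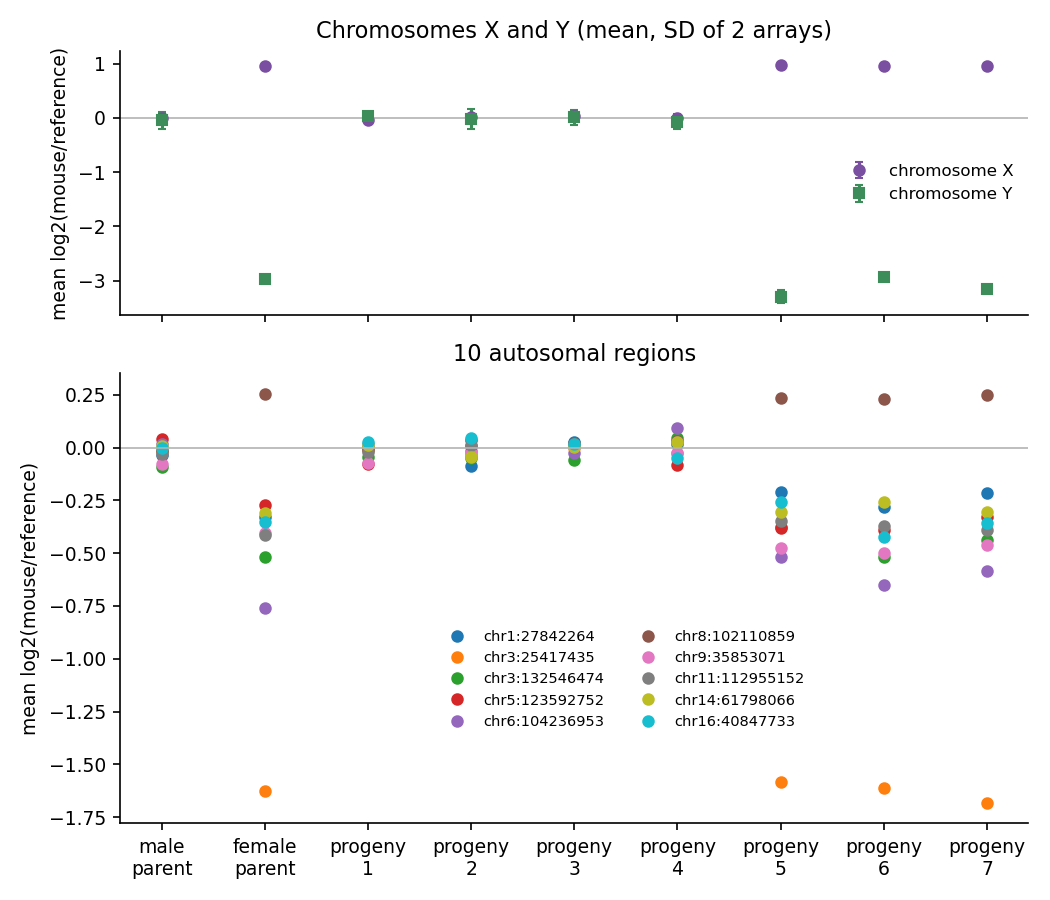
Upper panel, mean log2 ratio of mouse over reference on chromosomes X and Y (vertical axis) per mouse (horizontal axis), with bars for the SD of 2 arrays; lower panel, the mean log2 ratio of the same mice at the 10 autosomal regions with intervals in the female parent and progeny 5, 6 and 7. The chromosome 3 loss lies between -1.68 and -1.58 in those 4 mice, whose X ratios lie between 0.95 and 0.97.

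At other parental regions all 7 progeny lay between their parents, and the number called depended on the call conditions. On chromosome 13 (95704529 to 95712034, 4 probes) the male parent had 0.58 ± 0.13 and the female parent 0.10 ± 0.05. The progeny lay there between 0.22 and 0.43, and 6 were called. On chromosome 19 (39810427 to 39940605, 4 probes) the female parent had -0.61 ± 0.31 and the male parent 0.08 ± 0.12. The progeny lay there between -0.37 and -0.20, and 4 were called. In all, 242 regions were called in exactly 1 parent, 127 in the male and 115 in the female parent, and 62 of them were called in the same direction in at least 1 progeny mouse. The other 180 were called in 0 of 7 progeny, each with an exact binomial p of 0.0156, the smallest that 7 progeny allow (adjusted p = 0.0210), and 172 of these 180 had under 6 probes, while the chromosome 8 gain, with progeny just under the minimum, is also among them. Among the 228 regions of under 6 probes, 90 of 1596 pairs of region and progeny mouse were called (5.64%), and among the 4 regions of 10 or more probes 9 of 28 (32.1%). These 4 include the chromosome 8 gain (0 of 7) and the chromosome 14 loss (3 of 7) with intervals in progeny 5, 6 and 7. Short regions of that set, such as those on chromosomes 3, 6 and 9, are among the 228. The 62 regions and both shares therefore mix that set with other parental regions.

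Intervals per mouse numbered 127 in the male parent, 120 in the female parent and 122 to 251 in the progeny, and most were at the lower limit of length. Of 1745 intervals, 1351 held 3 probes and 60 held 10 or more. The same search on probes in random order gave a mean of 1264 intervals of 3 probes and 2 of 10 or more, and a search on the dye-only signal gave 355 and 16. Of the intervals of 3 to 5 probes, 81.3% held a probe that was not well above background on some array, against 5.22% for intervals of the same lengths if such probes, 1.66% of the autosomal probes, lay at random. When they were left out the mean per mouse fell from 194 to 49.9 intervals. The progeny averaged 214 ± 42.0 intervals (SD, n = 7) against 123.5 in the parents (n = 2, exact permutation test, two-sided p = 0.111, where 0.0556 is the smallest p possible). The parents had low noise (0.105 in the male and 0.099 in the female) and were scanned apart from the progeny. Progeny 3, with noise of 0.103, had 122 intervals, and the other progeny had noise of 0.114 to 0.123. Group thus cannot be separated from noise and scan day here. On chromosome X, centred on each mouse's own median, 1 interval of 3 probes was found, in the male parent.

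**Figure D3:**
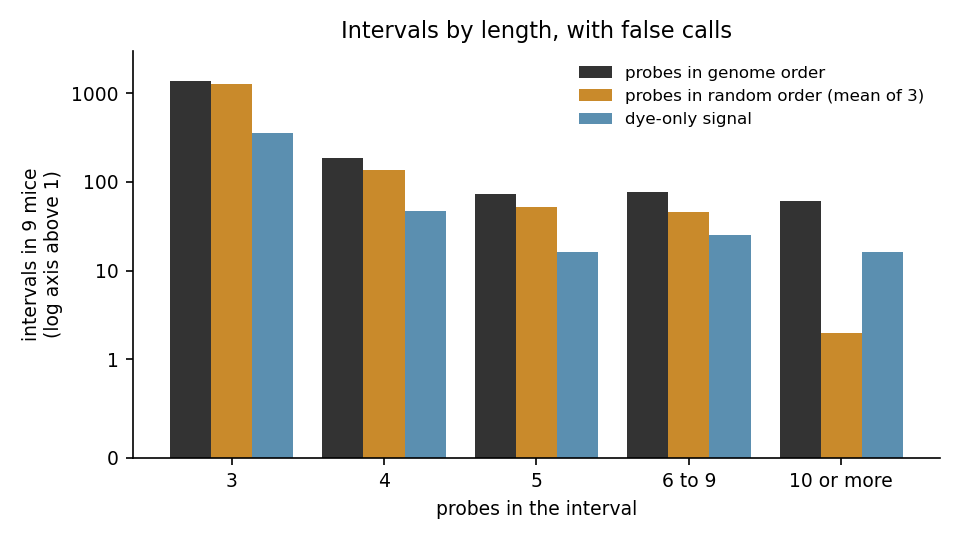
Number of intervals in the 9 mice (vertical axis, logarithmic above 1) by the number of probes they hold (horizontal axis) with probes in genome order, in random order (mean of 3 orders) and on the dye-only signal. At 3 probes the genome order gave 1351 and the random order 1264, and at 10 or more probes 60 and 2, with 16 on the dye-only signal.

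Changes present in progeny and absent from both parents were the target of the screen. In all, 1212 regions were called in at least 1 progeny mouse and in neither parent, and 1071 of them also differed from each parent by at least 0.25 in a called progeny mouse. Of the 1212, 1135 held under 6 probes. The 9 short regions among the 10 with the highest scores were losses. A loss lowers the signal of its own probes and can make them dim, so leaving out dim probes could also remove a true loss. In 6 of the 9 the ratio came within 0.25 of 0 once probes not well above background were left out: on chromosome 1 at 120862932 (progeny 4, -0.80 to -0.05) and 6925597 (progeny 5, -0.67 to -0.06), chromosome 3 at 111007266 (progeny 5, -0.74 to 0.00029), chromosome 13 at 54533147 (progeny 3, -0.43 to -0.06), chromosome 14 at 52753438 (progeny 7, -0.59 to -0.17) and chromosome 17 at 15338178 (progeny 3, -0.39 to -0.0062). The loss on chromosome 16 at 36139356 in progeny 6 moved from -0.79 to -0.38 in that way and to -0.13 under normexp, so that under normexp 7 of the 9 came within 0.25 of 0. The remaining pair kept their values without dim probes, on chromosome 3 (72279041 to 72282929, 3 probes) at -0.80 ± 0.63 (SD of 2 arrays) in progeny 2 and on chromosome 2 (157244961 to 157249495, 3 probes) at -0.72 ± 0.79 in progeny 4, and for both the arrays of opposite dye differed by more than the loss itself. The other of the 10 was the chromosome 14 segment described above, in which the parents stood at -0.24 and -0.23.

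When only intervals of at least 10 probes were joined, a limit chosen after seeing the data, 9 regions were called in progeny and in neither parent. In the main joining 8 of them were called so. The chromosome 11 region held 18 probes there and was not called, with progeny 7 at 0.23. Of the 9 regions, 4 differed from each parent by at least 0.25. These 4 were a pair of gains on chromosome 15 of progeny 7 (starting at 22989802 and 28354372, at 0.25 and 0.26), and losses on chromosomes 19 and 17. Centring each chromosome on its own median, also chosen after seeing the data, took the intervals of progeny 7 from 216 to 189. It also took these gains to 0.19 and 0.20, below the call minimum, and over the level of 0.10 of their part of chromosome 15 they stood at 0.15 and 0.16. The loss on chromosome 19 was in progeny 7 (32837992 to 32855441, 10 probes) at -0.30 ± 0.07 (SD of 2 arrays). The loss on chromosome 17 was in progeny 5 (26632933 to 26651577, 11 probes) at -0.27 ± 0.05. The other five lay under 0.25 from a parent: gains of progeny 7 on chromosome 15 (4572778 and 23970899, both at 0.25 and 0.19 after centring, with 0.11 and 0.05 in the female parent) and chromosome 11 (3058134, 0.26, with 0.12), a gain of progeny 6 on chromosome 5 (5659401, 0.25, with 0.11), and the chromosome 14 segment found in all 9 mice. Of the 60 intervals of 10 or more probes, 52 lay in regions with intervals in several mice and 8 in regions of 1 mouse. The dye-only signal, which is noisier than the mean, gave 16 intervals of that length, and random order gave 2. The regions in progeny and in neither parent are candidates of a primary screen. The secondary arrays and quantitative assays named in the design text were not used here.

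Whole chromosomes were compared by their median log2 ratio. In 8 mice the medians of all 19 autosomes lay between -0.0059 and 0.0054. In progeny 7 the medians of chromosomes 15, 7, 17 and 10 were 0.061, 0.046, 0.044 and 0.030, each positive on both arrays, and the 13 chromosomes without such a shift lay between -0.016 and -0.0072. Chromosome 6 of progeny 7 stood between them at 0.0078 (0.0031 and 0.011 on its arrays), above every median of the other 8 mice. Chromosome 5 of progeny 7 stepped from -0.014 to 0.06 at 112.0 Mb, and chromosome 15 from 0.10 to 0.04 at 35.2 Mb. These shifts are small beside the noise of single probes, which was 0.12 in this mouse, and rest on medians over many probes of 1 mouse.

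**Figure D4:**
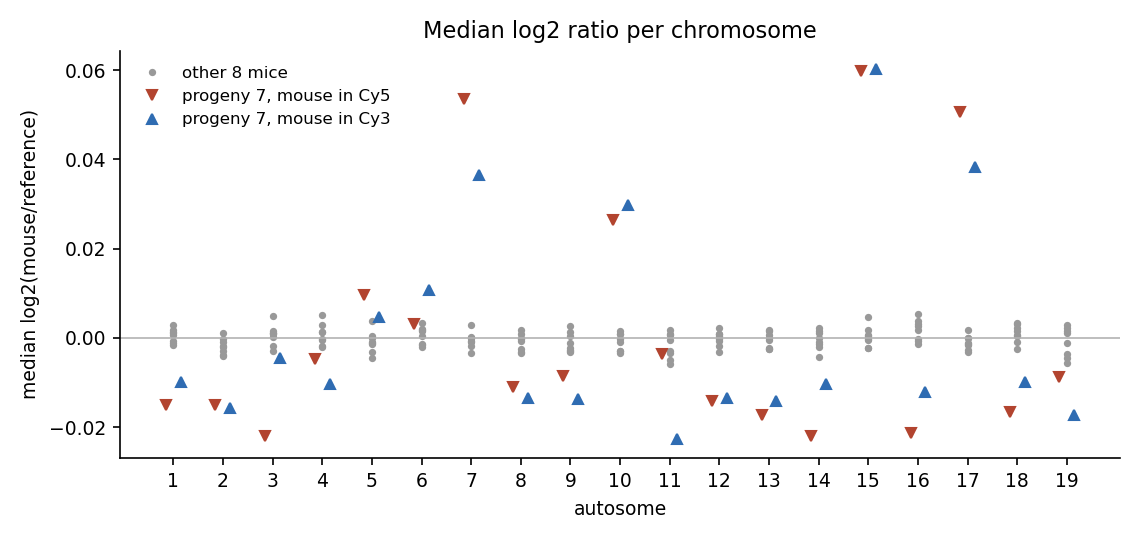
Median log2 ratio of mouse over reference (vertical axis) for each autosome (horizontal axis), with grey dots for the other 8 mice and triangles for both arrays of progeny 7. The 8 mice stay between -0.0059 and 0.0054, while chromosome 15 of progeny 7 reaches 0.06 on both arrays.

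**Figure D5:**
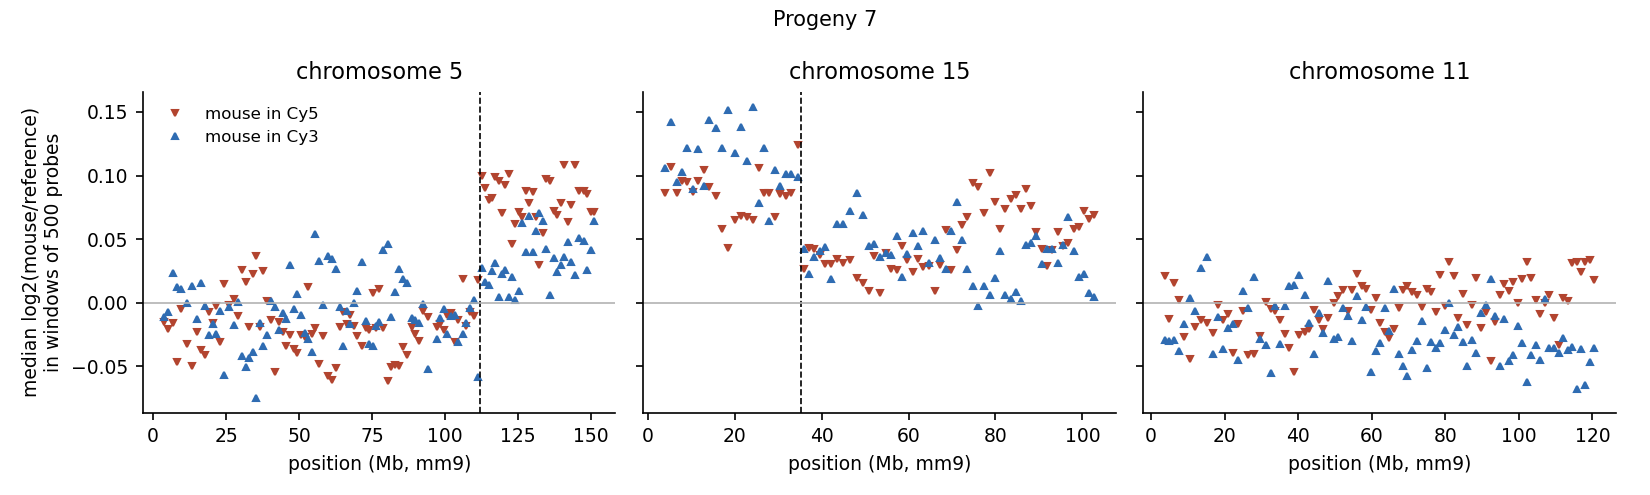
Median log2 ratio of mouse over reference in windows of 500 probes (vertical axis) along chromosomes 5, 15 and 11 of progeny 7 (horizontal axis, Mb on mm9), with triangles for the arrays with the mouse in Cy5 (down) or Cy3 (up) and a dashed line at the fitted step. The steps lie at 112.0 Mb on chromosome 5 and 35.2 Mb on chromosome 15.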

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

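The tests of dye bias, a gain in part of the cells, a single level on chromosome 15, a wave of the same size in all mice, scan day, inheritance from the female parent, sequence shared with the sex chromosomes, noisier arrays and dim probes were chosen only after the result was seen. About 1 in 20 groups would be singled out by chance at the level used, and 54 quantities were tested over the 7 progeny, of which 22 stood apart.

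Progeny 7 stood apart from the other progeny in the median log2 ratio of 13 chromosomes. It was raised on chromosomes 15 (0.061), 7 (0.046), 17 (0.044) and 10 (0.030). It was lowered on chromosomes 1 (-0.012), 2 (-0.015), 3 (-0.014), 8 (-0.011), 12 (-0.013), 13 (-0.015), 14 (-0.015), 16 (-0.016) and 18 (-0.012), which centring on the autosomal median produces when other chromosomes rise. Within the raised part of chromosome 15, at a level of 0.10, progeny 7 stood apart at 2 segments starting at 4572778 (0.25) and 28354372 (0.26), which are 0.15 and 0.16 over that level. Progeny 7 also stood apart at a loss on chromosome 19 starting at 32837992 (-0.30).

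Dye bias would turn the sign between the arrays, and the lowest of the 8 medians of the raised chromosomes was 0.026. Dim probes would carry the shift, and the lowest shift of chromosome 15 over the 13 unshifted chromosomes in any quartile of probe brightness was 0.071. A wave of the same size in all mice would raise the 4 chromosomes elsewhere too, where their highest median was 0.0046, and a wave in the arrays of this mouse would roughen its 13 unshifted chromosomes, where the spread of window medians was 0.775 of the highest among the other mice. A wave of common shape but different size stays open, since the medians of the 19 autosomes correlated at r = 0.522 with those of progeny 5, between the bounds set for either answer. With the remaining mice r lay between -0.360 and 0.083, so a shape common to all arrays was not seen. A gain of chromosomes 7, 10 and 17 and of the end of chromosome 5 in part of the tail cells remains a hypothesis. The step on chromosome 5 fell at places 0.430 Mb apart on both arrays, but the level past it was lower with the mouse in Cy3. Under this hypothesis, 1 extra copy would correspond to 8.39% of cells for chromosome 7, 8.09% for chromosome 17 and 5.98% for chromosome 10. Chromosome 15 had a step of -0.055, against at most 0.018 in size in the other 8 mice, which argues against 1 extra whole copy in a single share of cells, and the source of its 2 levels stays open, as does that of the small shift of chromosome 6 (0.0078). The arrays share 1 DNA extract, so an effect of that extract could not be excluded, and GC content was not tested.

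The 10 regions with intervals in progeny 5, 6 and 7 made up another pattern: of 23 regions with intervals in exactly 3 progeny, picked without regard to the parents, 10 lay in this set and at most 2 in any other, and 10 of the 10 had an interval in the female parent and 0 in the male parent. Scan day would affect both parents alike, and the smallest difference between the parents at the 10 regions was 0.27. Independent inheritance of autosomal regions would spread the carriers over 35 possible sets of 3 progeny. Instead, 10 of 11 such regions shared 1 set (one-sided exact binomial p = 1.36e-13 after multiplication by 35), which argues against such inheritance for these 10. Progeny 5, 6 and 7 are those with raised X ratios, a set that 1 random draw of 3 progeny would give with a chance of 0.0286, so sequence shared with chromosome X (for the gain) or Y (for the 9 losses) is a candidate source. This hypothesis arose from the same regions, and probe sequences were not used here, so the matches themselves were not examined.

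Short intervals seen in 1 mouse made up another pattern. Random order of the probes gave 90.3% as many intervals of 3 to 5 probes as genome order, so single-probe noise is a likely source. Of the observed ones 81.3% held a dim probe, but a loss can itself make its probes dim. For losses, this share therefore cannot separate noise at dim probes from a true loss. Variants carried by a parent should pass to a share of the progeny near 0.5, but 5.64% of pairs were called. Noisier arrays stay open: over the 9 mice, intervals and noise gave Spearman's rho = 0.6 (exact permutation p = 0.0968) and Pearson's r = 0.903 (exact permutation p = 0.0126), and r = 0.766 without the female parent and progeny 3, the 2 mice farthest in noise. Within the 4 scan days that hold 2 mice, the noisier mouse had more intervals on 3 (by 7, 103 and 19) and fewer on day 2 (-6).

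Progeny 3 stood apart by its low number of intervals, 122. Single progeny stood apart at 5 other segments: progeny 4 on chromosome 1 at 120862932 (-0.80) and on chromosome 2 at 157244961 (-0.72), progeny 2 on chromosome 3 at 72279041 (-0.80), and progeny 5 on chromosome 3 at 111007266 (-0.74) and on chromosome 17 at 26632933 (-0.27). The regions were chosen for high values in a mouse, which makes such a gap likely whatever its source, and the chromosome 3 loss in progeny 5 became 0.00029 without dim probes.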

How the results depend on the processing

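The numbers of short regions depended on the processing, whereas the number of regions shared by all mice included was 2 under all but 2 alternatives (3 without dim probes, 1 at a minimum of 0.4). Both of the 2 main regions were among them except at a minimum of 0.4 and with the mouse in Cy5 alone, where 1 was. The main values were 194 intervals per mouse, 1490 regions, 1212 in progeny and neither parent, 1071 of these 0.25 from each parent, and 62 parental regions found in progeny. In this order, normexp gave 27.3, 158, 116, 99 and 18, the filter on dim probes 49.9, 356, 285, 253 and 25, a score of at least 5 gave 529, 4059, 3315, 2526 and 94, a score of at least 8 gave 35.8, 254, 184, 179 and 23, and at least 5 probes 79.7, 612, 522, 359 and 10. Arrays with the mouse in Cy5 alone gave 123, 918, 408, 389 and 338, and in Cy3 alone 124, 965, 606, 557 and 244. Chosen after seeing the data, at least 10 probes gave 6.67, 16, 9, 4 and 3, and a median of the probes of at least 0.25 gave 86.2, 692, 578, 520 and 34. Parental regions found in progeny numbered 14 at a minimum of 0.4 and 158 without a condition on single arrays. Fewer or more intervals follow from stricter or looser thresholds by construction; for the other settings the cause was not tested. The other alternatives, among them the scanner's log ratio, the value table, reciprocal overlap, window noise and centring of each chromosome (chosen after seeing the data), stayed within 1.5 times of these counts, where reciprocal overlap acts on regions only. Without single progeny, regions ranged from 1286 to 1405.

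Against the reference male, the limma count of 117 probes became 177 with 18 arrays, the mouse as a random block and a dye term. That fit weighed both arrays of a mouse almost as separate samples. The count ranged from 77 to 97 without single progeny, with 77 without progeny 5. Against parents, 0 became 1 without the female parent, where the lone parent is assumed to vary like the progeny, and ranged from 0 to 1 without single progeny. With scan day as a random block, the counts were 119 against the reference male and 0 against parents, where day and group cannot be separated. The X ratio of the female parent moved from 0.95 to 0.74 under normexp, and its Y ratio from -2.96 to -0.70 under normexp, -1.26 without dim probes and -2.97 in the value table. Of 88 values of the 22 named regions under 4 alternatives (normexp, the scanner's log ratio, the value table and no dim probes), 86 kept their sign. Both that turned belong to progeny 5 on chromosome 3 at 111007266, at 0.051 under normexp and 0.00029 without dim probes. In all, 72 moved by less than the SD between arrays. The scanner's log ratio and the value table hold the same measurements as the main values and were bound to stay close. Every value that turned or moved further came from normexp or the dim filter. That filter cannot change a region without dim probes. GC correction and the gene lists were not run. No paired analysis was possible because parents and progeny are different animals of 1 family, and no progeny mouse is matched to a single parent. Signal over background of 2.80 to 5.84 limits what single dim probes show.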

Other observations

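The hypothesis below was tested only after the result was seen. The gain and the loss on chromosome 4 of the male parent lie 22.6 Mb apart, and 6 of 7 progeny carried exactly 1 of them, namely the loss in progeny 1, 3, 4 and 6 and the gain in progeny 5 and 7, while progeny 2 carried neither. This would follow if the changes lay on opposite copies of the male parent's chromosome 4, with a crossover in progeny 2 as a candidate explanation for the exception. With 7 progeny the share did not differ from 0.5 (exact two-sided binomial p = 0.125). A share of 0.5 is that of changes passed independently, so this test cannot decide between the same copy and opposite copies. On the same copy, each of the 6 progeny with exactly 1 change would need a crossover between them. Their number argues against the same copy, but crossover rates were not measured here.

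Some segment means lie near simple copy ratios, and others do not. The chromosome 4 gain of 0.58 equals the log2 of 3 copies over 2 (0.58), the level of a single added copy in a carrier. The chromosome 15 mean of -0.53 in all 9 mice lies near the log2 of 2 over 3 (-0.58). The chromosome 7 mean of -0.40 in all 9 mice and the chromosome 4 loss of -0.39 in the male parent lie near that of 3 over 4 (-0.42). On chromosomes 7 and 15, extra copies in the shared reference would give the same ratios as fewer copies in the mice. The means of 0.24 on chromosome 12 and -0.24 on chromosome 14 (53387255), and 0.26 on chromosome 8 in the female parent, lie near none of the ratios computed. The nearest were 0.32 for 5 over 4 and -0.42 for 3 over 4. In the progeny, single probes reached 0.45 in the chromosome 12 segment and -0.64 in the chromosome 14 segment. Both means may thus mix several levels and need not stand for 1 copy ratio. Copy numbers were not measured, and the X ratio of 0.95 for a 2-fold difference shows slight compression.

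At 40.2 kb on chromosome 11 (3058134 to 3098381, 17 probes), the 9 mice spread from -0.16 in the male parent to 0.26 in progeny 7, with 0.12 in the female parent and 0.16 and 0.18 in progeny 4 and 5, without falling into separate levels.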
